A study of Mus musculus with 2 samples.

How the data were processed

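Total RNA was extracted with TRIzol from cultures labelled primary microglia, and poly(A) RNA was captured on oligo(dT) beads, fragmented, reverse transcribed with random hexamers and made into libraries with selected fragments, per the labels' protocols. The labels' protocols name no step that marks strand, so reads of overlapping antisense genes cannot be told apart. There were 2 libraries: 1 DMSO control and 1 given 1600 μM iron and 1 μM RSL3. Groups were taken from the sample titles, and the columns of the table were assigned by the library names in the sample descriptions. All columns of values were assigned.

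The table deposited by the authors holds FPKM values (fragments normalised to transcript length and to the mapped fragments of the library) for 23466 rows. The submitters' processing notes name HISAT2, StringTie, DESeq2 and edgeR and the genome build GRCm38. Their versions, the annotation release and any filters are not given in the sources used here, and no comparison made by the authors was used. Of the rows, 22036 carried an Ensembl gene identifier, of which 22022 were found in GENCODE M21, a mouse annotation of the build GRCm38. The other 1430 rows were newly assembled loci without coordinates, which held 0.944% of the control and 1.01% of the treated FPKM total. In 27 rows the gene symbol had been turned into a date, and all 27 were restored through the identifier. A further 19 symbols stood on more than 1 row, and for these the row with the higher mean was used in gene lists. Coordinates are those of GENCODE M21 on GRCm38.

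FPKM is relative to the mapped fragments of a library, so genes that take a larger share lower all others. The FPKM totals were 385141 in the control and 429250 in the treated library, the 20 most abundant genes held 10.1% and 14.7% of them, and mitochondrially encoded genes 4.82% and 6.02%. Genes at 1 FPKM or more numbered 11481 in the control and 10884 in the treated library. No read counts were used. For genes with a single annotated transcript, the product of FPKM and transcript length clustered at a step of 60.7 in the control and 55.6 in the treated library. Taking a step as 1 fragment makes the treated library 1.09 times as deep. Among such genes below 3.5 steps, 35.3% and 37.9% of values lay within 0.05 of a whole number of steps, against 10% if they were evenly spread. Whole fragments were therefore not recovered. No count model was applied, apart from the interval for Per2 and the simulation, which rest on fragments estimated from the steps. At these depths 1 FPKM on a transcript of 1000 bases then corresponds to about 16.5 and 17.98 fragments. Intervals cover counting error only.

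Each gene was compared as log2(FPKM + 1) of the treated minus the control library, over genes with at least 1 FPKM in either. With 1 library per condition no test between conditions was possible, and genes past 2-fold were counted by size alone. The 39 gene lists were fixed before the data were examined, as were the rule for named genes and the alternatives. A list with at least 5 measured members was described by its median, and by the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. Of the lists, 37 had enough members, and 1.85 of 37 would lie outside the central 95% by chance if members were independent. Members of a list can move together, and 59 genes stood in more than 1 list, so more could lie outside by chance. Percentiles describe these libraries and are not p-values. Genes named in the text were the 12 with the largest and the 12 with the smallest log2 change among annotated genes at 5 FPKM or more. They also included up to 2 members per direction past 2-fold from each list (or its 2 most abundant members where none passed), the core clock genes and 10 ferroptosis and iron genes whatever their values, and the 5 most abundant genes per library. This gave 105 genes, some of which are not reported here. The marker lists of pan-myeloid and of mesenchymal genes were added after the fixed marker lists had been seen, and before their own values had been. A list of YAP and SRF targets was added after 6 of its members had been seen.

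The calculations were tested on simulated libraries with fragments drawn from the control values, the annotated lengths and the estimated depths, with 200 genes changed. The changed genes were all drawn from those at 5 FPKM or more in the control, so recovery of weaker genes was not tried. Of these, 100% of genes raised 3-fold were recovered, as were 98% of those lowered 3-fold and 100% of those changed 6-fold either way. The simulated libraries had 11253 tested genes. Of 100 unchanged lists of 20 genes, 4% lay outside the central 95%. These lists were random genes with counting noise only, so the figure leaves out members that move together. Alternatives covered the pseudocount, the filter, the scale and the size rule, and random lists matched on transcript length, in 10 bins of expression and 5 of length, were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.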

Results

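The data were bulk RNA-seq expression values of mouse cells labelled primary microglia, the resident macrophages of the central nervous system. The 2 libraries were a vehicle control given DMSO and a culture given 1600 μM iron together with 1 μM RSL3. RSL3 is a small molecule that inactivates GPX4, the enzyme that reduces lipid hydroperoxides, and the combination was used to induce ferroptosis, an iron-dependent form of cell death. Each condition had 1 library, so no difference below has a replicate check, an error or a p-value. The differences describe these libraries and not the conditions. A gene was measured when it reached 1 FPKM in either library, which 11771 genes did, and it was called higher or lower only by a size rule of 2-fold. All log2 changes are treated against control, on the scale of log2(FPKM + 1), which understates the change of weakly expressed genes. Low values lay partly on steps: for genes with 1 annotated transcript, 35.3% in the control and 37.9% in the treated library were within 0.05 of a whole step. An even spread would give 10%. If 1 step is 1 fragment, 1 FPKM on a transcript of 1000 bases stands for about 16.5 fragments in the control and 17.98 in the treated library. The treated library was then 1.09 times as deep.

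The overall comparison asked how the transcriptome of the culture given iron plus RSL3 differed from that of the control. The 2 agents were given together, so their effects cannot be told apart. Ferroptosis itself was not measured in the values used here. Of the 11771 genes, 500 were at least 2-fold higher and 1384 at least 2-fold lower in the treated library, and 9887 lay between. On the scale of log2(FPKM + 1), the differences of large size were mostly increases: 165 genes were at least 4-fold higher and 26 at least 4-fold lower. That scale limits falls of weakly expressed genes, and the 4-fold counts were not run with a smaller pseudocount. Across genes, which are not independent replicates, the libraries correlated with a Pearson r of 0.92 and a Spearman rho of 0.92. The median log2 change of all measured genes was -0.38, with an interquartile range from -0.73 to 0.01. The 2-fold counts depend on this shift, because centring on the median ratio of abundant genes gave 665 higher and 765 lower genes and moved the median of all genes to -0.19, while equal totals moved it to -0.51. List medians are therefore set against random lists of matched expression, which carry the same shift. In a simulation that drew both libraries from the control values with counting noise alone, 2 of 11053 unchanged genes passed 2-fold. That figure leaves out the shift between the libraries and variation between cultures, so it is no noise level for the 2-fold counts.

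**Figure D1:**
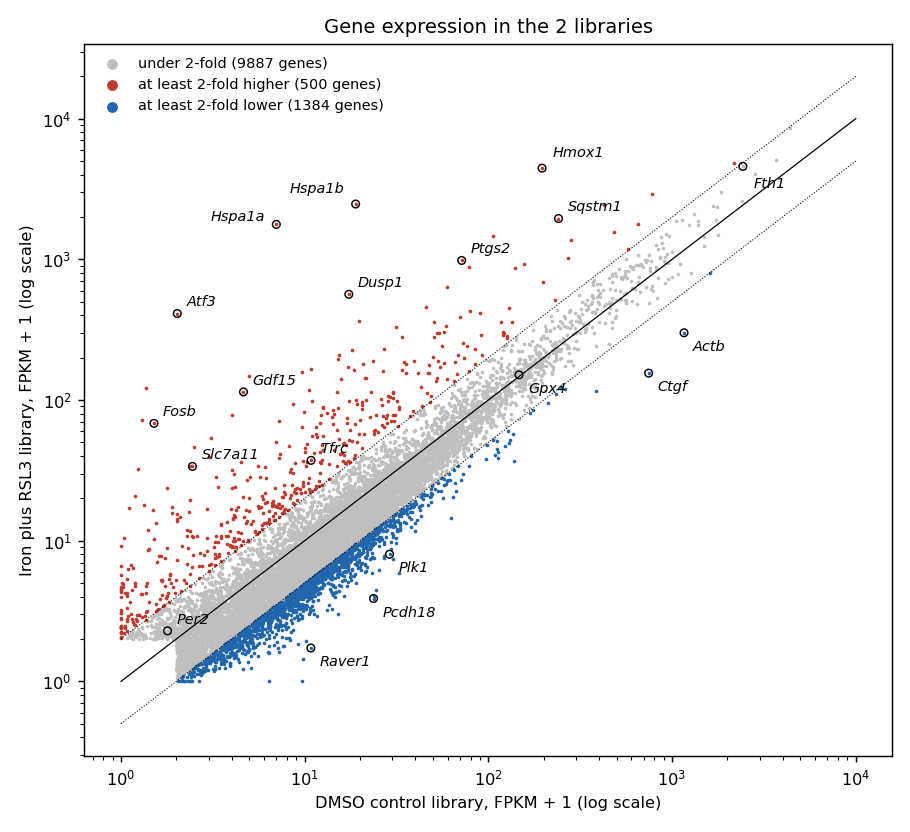
FPKM + 1 of each measured gene in the DMSO control library (x axis) and the iron plus RSL3 library (y axis), both on log scales. The solid line marks equal values, the dotted lines mark 2-fold, and circled genes are named; 500 genes lie above the upper line and 1384 below the lower line.

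The 12 named genes with the largest increase belonged mainly to the heat shock and immediate early programmes. The inducible HSP70 chaperone gene Hspa1a was at 6.01 FPKM in the control and 1771 FPKM in the treated library, a log2 change of 7.98. Its near-identical neighbour Hspa1b went from 17.9 to 2473 FPKM, and reads may be split between these copies, so their separate values are uncertain. Atf3, a stress-induced transcription factor, was at 1.03 and 411 FPKM, a log2 change of 7.67. The others were Fosb (5.50), Dusp1 (5.02), Gem (4.89), Ankrd37 (4.69), Gdf15 (4.62), Hmox1 (4.50), Fos (4.28), Osgin1 (4.22) and Dnajb1 (4.20), each given as a log2 change. The 12 with the largest decrease reached smaller sizes. Raver1, an RNA-binding protein gene, was at 9.81 FPKM in the control and 0.73 FPKM in the treated library, a log2 change of -2.65. Pcdh18, a protocadherin gene, was at 22.7 and 2.88 FPKM, and Rgs4, a regulator of G-protein signalling, at 22.8 and 3.04 FPKM. Ctgf, a matricellular growth factor gene, was the most abundant of them, at 745 FPKM in the control and 154 FPKM in the treated library. The remaining ones were Chst12 (-2.47), Lmod1 (-2.44), Nynrin (-2.38), Magee1 (-2.33), Fignl1 (-2.30), Zbtb45 (-2.16), Pcyox1l (-2.10) and Phldb2 (-2.10).

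Of the 20 measured suppressors, 5 were at least 2-fold higher, none was 2-fold lower and 15 lay between. Slc7a11, the cystine importer subunit, was at 1.45 FPKM in the control and 32.8 FPKM in the treated library, 22.6 times as high. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, was at 17.1 and 225.7 FPKM. Gpx4, the target of RSL3 (chromosome 10, 80047166 to 80056439, GRCm38), was at 145.8 FPKM in the control and 149.97 FPKM in the treated library, a log2 change of 0.04 that became -0.11 when both libraries were set to the same total. The median log2 change of the suppressors, -0.18, turned to 0.028 after centring and lay at the 75.5th percentile of random lists of matched expression.

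Among 17 measured ferroptosis drivers and lipid peroxidation enzymes, 6 were at least 2-fold higher and 1 was lower. Hmox1, the haem-degrading enzyme that releases iron (chromosome 8, 75093621 to 75100589), was at 195.1 FPKM in the control and 4450.3 FPKM in the treated library, 22.8 times as high. It was among the 5 most abundant transcripts of the treated library. Ptgs2, the cyclooxygenase gene widely used as a ferroptosis marker, was at 70.6 and 981.7 FPKM, 13.9 times as high. Chac1, a glutathione-degrading enzyme, was at 9.94 and 54.9 FPKM. Acsl4, which activates polyunsaturated fatty acids for membrane phospholipids, was at 20.5 and 21.3 FPKM, a log2 change of 0.05 that became -0.10 with equal totals. The median of the list, 0.41, lay at the 99.93rd percentile of matched random lists. Its size depended on the processing: it was 0.25, at the 98.8th percentile, among members at 5 FPKM or more. Without the mitochondrial and 20 top genes it was 0.17, at the 99.7th.

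Genes of iron handling went both ways. Of 24 measured, 5 were at least 2-fold higher and 1 was lower, and the median of -0.16, which turned to 0.031 after centring, lay at the 81.6th percentile. The ferritin subunit genes were abundant in both libraries: Fth1 was at 2428 and 4582 FPKM and Ftl1 at 2170.3 and 4817 FPKM, log2 changes of 0.92 and 1.15. Ftl1 fell just under 2-fold with equal totals and Fth1 passed it after centring. Tfrc, the transferrin receptor that takes up iron, was 3.69 times as high in the treated library (9.83 and 36.3 FPKM). Slc40a1, the iron exporter ferroportin, was at 1.39 and 4.78 FPKM. Aco1, which encodes iron regulatory protein 1, was at 22.1 and 9.76 FPKM, 2.26 times lower, and missed 2-fold after centring on the median ratio. Among 6 measured metallothionein and zinc response genes, 4 were at least 2-fold higher, led by Mt1 (139.4 and 869.9 FPKM) and Mt2 (155.1 and 923 FPKM). That list had a median of 1.22, at the 99.98th percentile.

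Antioxidant and stress response genes were higher as groups. Of 24 measured NRF2 targets, 12 were at least 2-fold higher and none 2-fold lower, with a median log2 change of 1.06. Osgin1, an oxidative stress response gene, was at 1.48 and 45.4 FPKM, and Hmox1 belongs to the same list. Of 23 ATF4 and CHOP response genes, 12 were higher and 1, the tryptophanyl-tRNA synthetase gene Wars, was lower (30.3 and 12.7 FPKM, under 2-fold after centring), with a median of 1.01. Of 18 heat shock genes, 16 were higher and none lower, with a median of 1.90. Of 18 p53 targets, 11 were higher and none lower, with a median of 1.36. The cytokine gene Gdf15 was at 3.64 and 113.2 FPKM and the antiproliferative gene Btg2 at 14.7 and 140.7 FPKM. Of 22 immediate early genes, 18 were higher and none lower, with a median of 2.79, led by Atf3 and Fosb. The medians of these 5 lists each lay above all 10000 matched random lists. Atf3, Sesn2 and Slc7a11 each belong to 2 of these lists, so their counts are not independent.

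Chaperones of the endoplasmic reticulum did not share this shift. Of 18 measured, 2 were at least 2-fold higher: Dnajb9, a co-chaperone gene, at 14.1 and 113.4 FPKM, and Herpud1, a gene of endoplasmic reticulum-associated degradation, at 29.2 and 102.3 FPKM. The median of the list was -0.08, at the 56.04th percentile, and turned to 0.13 after centring. Of 26 glutathione and thioredoxin enzymes, 4 were higher, including Gclc and Gclm (11.1 and 67.5 FPKM), with a median of 0.15 at the 95.9th percentile, or the 97.9th with a pseudocount of 0.1 FPKM. Of 16 selenoprotein genes, 1, Txnrd1, was higher (88.5 and 412.9 FPKM), and the median was -0.05, at the 67.5th percentile, and 0.17 after centring. Among 18 genes of apoptosis, pyroptosis and necroptosis, Bcl2l11, a pro-apoptotic BH3-only gene, was higher (3.82 and 12.3 FPKM). In the other direction 2 genes were lower, among them Bid (26.6 and 12.5 FPKM), which missed 2-fold after centring. The median of that list was -0.41, at the 21.8th percentile, and became -0.09 at the 89.5th among members at 5 FPKM or more.

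**Figure D2:**
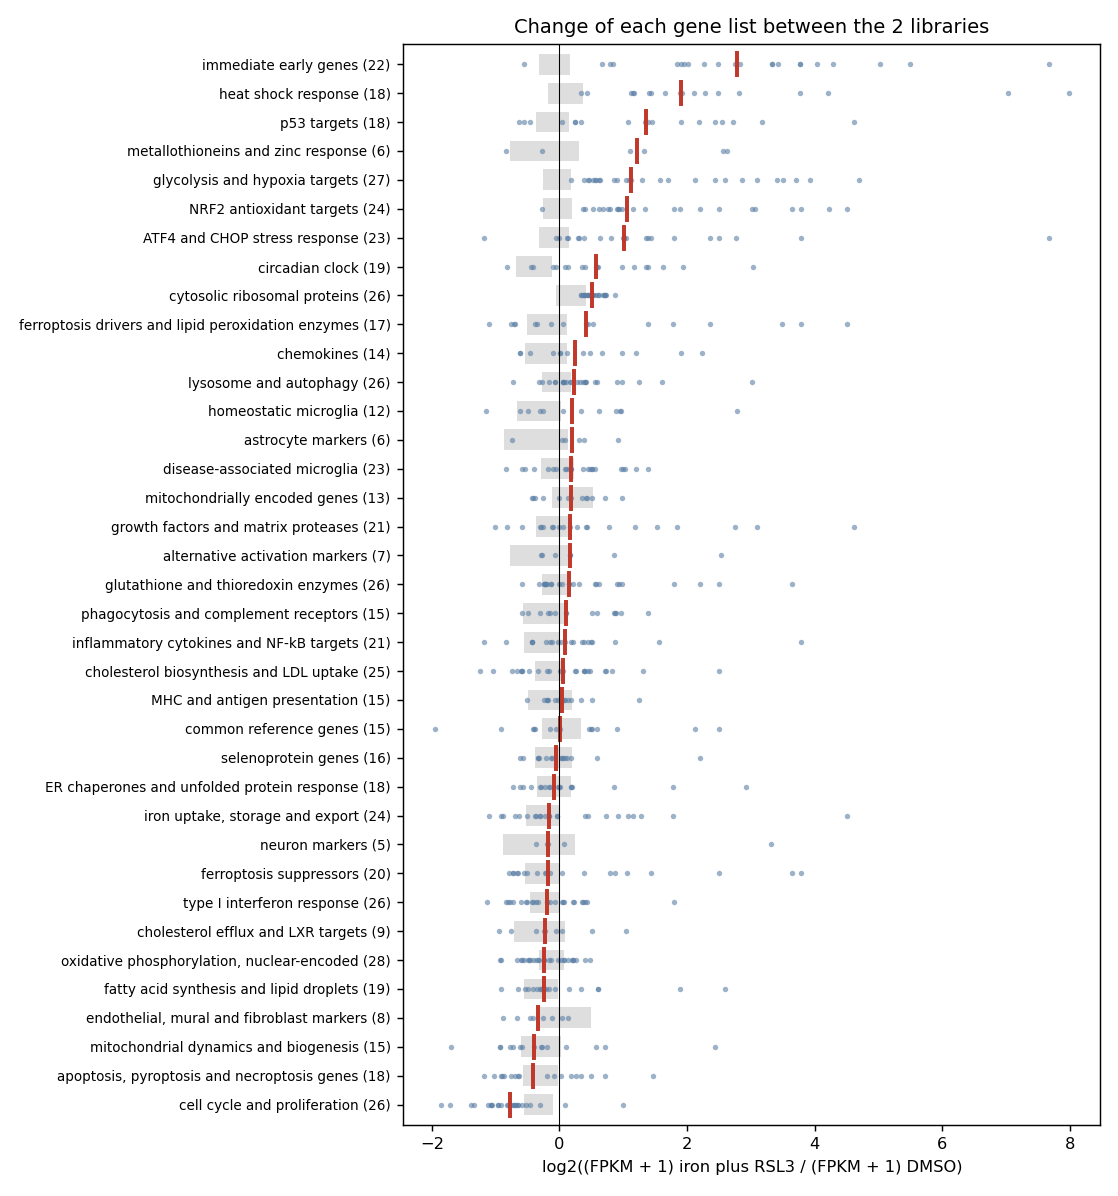
Log2 change (x axis, treated against control on FPKM + 1) of the measured members of each of 37 gene lists fixed in advance (rows, number of measured members in parentheses). Points are genes, red bars are list medians and grey bands span the central 95% of the medians of 10000 random lists matched on expression; the immediate early list has the highest median, 2.79, and the cell cycle list the lowest, -0.78.

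Glycolytic and hypoxia-inducible genes were higher together. All 27 measured members had a log2 change above 0 and 16 were at least 2-fold higher. The median of 1.13 lay above all 10000 matched random lists. Ankrd37, a hypoxia-inducible ankyrin repeat gene, was at 0.24 and 31.1 FPKM, and Ndrg1, another hypoxia-inducible gene, at 9.88 and 164.9 FPKM. Nuclear-encoded oxidative phosphorylation genes had none of 28 past 2-fold, with a median of -0.24 at the 13.9th percentile. The most abundant of them were Atp5b (457.3 and 449.6 FPKM, higher in the treated library after centring) and Cox4i1 (244.3 and 324.1 FPKM). None of the 13 mitochondrially encoded genes passed 2-fold. The median of these was 0.17, at the 52.6th percentile, with mt-Co1 at 4373 and 8591 FPKM, past 2-fold after centring, and mt-Atp6 at 1841 and 3024 FPKM. Of 15 genes of mitochondrial dynamics and biogenesis, Bnip3, a mitophagy receptor gene, was higher (33.7 and 186.3 FPKM) and Oma1, an inner membrane protease gene, was lower (6.53 and 1.31 FPKM). That list had a median of -0.39, at the 27.4th percentile.

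Cell cycle genes formed the only list of the 37 tested whose median lay below the 2.5th percentile. Of 26 measured, 8 were at least 2-fold lower and none 2-fold higher, with a median log2 change of -0.78 with 1 of 10000 matched random lists at or below it. Plk1, a mitotic kinase gene, was at 28.0 FPKM in the control and 7.01 FPKM in the treated library, and Ccna2, which encodes cyclin A2, at 30.5 and 8.63 FPKM. Cytosolic ribosomal protein genes moved little but uniformly. All 26 had a log2 change above 0 and none passed 2-fold, with a median of 0.51 at the 99.67th percentile. Rplp1 was at 1312 and 2099 FPKM, and Rplp0 at 1234 and 1747 FPKM.

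Circadian clock genes were examined because the wider study concerns Per2, a repressor of the clock. Per2 (chromosome 1, 91415982 to 91459324, GRCm38) was weakly expressed in both libraries, at 0.79 FPKM in the control and 1.28 FPKM in the treated library. Whole fragments were not recovered, so its fragment numbers are estimates that take a step as 1 fragment. With its longest annotated transcript of 5833 bases, these values correspond to about 76 and 135 fragments. The ratio was 1.63, with an exact 95% binomial interval from 1.22 to 2.18 that covers counting error only. On its shortest transcript, of 231 bases, they correspond to about 3 and 5 fragments and an interval from 0.297 to 9.83, so the precision depends on the length used. Per1 (9.49 and 14.7 FPKM), Cry1 (5.71 and 7.90 FPKM), Arntl (24.4 and 37.7 FPKM), Clock (6.52 and 4.66 FPKM) and Dbp (3.86 and 3.51 FPKM, a difference that changed sign after centring) also stayed within 2-fold. Per3 was at 2.41 and 0.93 FPKM, a log2 change of -0.82 that became -1.29 with a pseudocount of 0.1 FPKM. Of the 19 measured clock genes, 6 were at least 2-fold higher and none 2-fold lower. Ciart, a clock repressor gene, was at 1.38 and 18.4 FPKM, and Nr1d1, which encodes the repressor REV-ERB alpha, at 11.4 and 46.8 FPKM. Nr1d2 (8.07 and 22.8 FPKM) and Cry2 (5.71 and 14.1 FPKM) were higher too. The median of the list, 0.58, lay above all 10000 matched random lists.

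Of 21 measured cytokines and NF-kB targets, 2 were at least 2-fold higher, Ptgs2 and the growth factor gene Csf3 (0.82 and 4.37 FPKM). The receptor gene Tlr2 was lower (20.8 and 8.603 FPKM) and missed 2-fold after centring. The median of 0.09 lay at the 99.3rd percentile, and it became -0.048 with equal totals and -0.024, at the 92.7th percentile, among members at 5 FPKM or more. Among 14 chemokine genes, 3 were higher and none lower, led by Cxcl2 (0.64 and 6.77 FPKM) and Cxcl10 (27.6 and 106.5 FPKM), with a median of 0.24 at the 99.5th percentile that became 0.07 at the 90.2nd among members at 5 FPKM or more. Of 26 type I interferon response genes, Mx2 was higher (5.85 and 22.7 FPKM) and Ifit1 was lower (34.6 and 15.3 FPKM), the latter under 2-fold after centring. The interferon median was -0.20, at the 64.8th percentile. Transcripts typical of all myeloid cells differed alongside these groups. Of 11 measured pan-myeloid genes, 3 were at least 2-fold higher and none 2-fold lower, and of 19 at 0.5 FPKM or more, 13 had a log2 change above 0.

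Most homeostatic marker genes of the labelled cell type were weak in both libraries. Of 25 homeostatic microglia genes, 13 stayed under 1 FPKM in both libraries and 5 reached 10 FPKM in both. Among these were Tmem119, Olfml3, Sparc and Tgfbr2, which are also expressed outside microglia. Disease-associated microglia genes were abundant, with medians of 120.3 and 152.1 FPKM over 25 members, many of which, such as the cathepsin genes Ctsb and Ctsd, are expressed in many cell types. The following genes were singled out after their values had been seen. Csf1r, the receptor on which microglial survival depends, was at 0.47 FPKM in the control and 0.39 FPKM in the treated library, P2ry12 at 0.05 and 0.04 FPKM, and Ptprc, the pan-leukocyte antigen CD45, at 0.07 and 0.11 FPKM. Aif1, which encodes IBA1, and Cx3cr1 were listed at 0 in both. In contrast, the fibroblast collagen genes Col1a1 (1002 and 753.7 FPKM) and Col1a2 (1109 and 928.2 FPKM), and Acta2, the smooth muscle actin gene (1273 and 805.3 FPKM), were among the abundant transcripts. Of 19 mesenchymal genes, 18 reached 10 FPKM in both libraries. Bgn, which encodes the matrix proteoglycan biglycan, was among the 5 most abundant transcripts of the control library, at 2403 and 2593 FPKM, a difference that changed sign with equal totals.

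**Figure D3:**
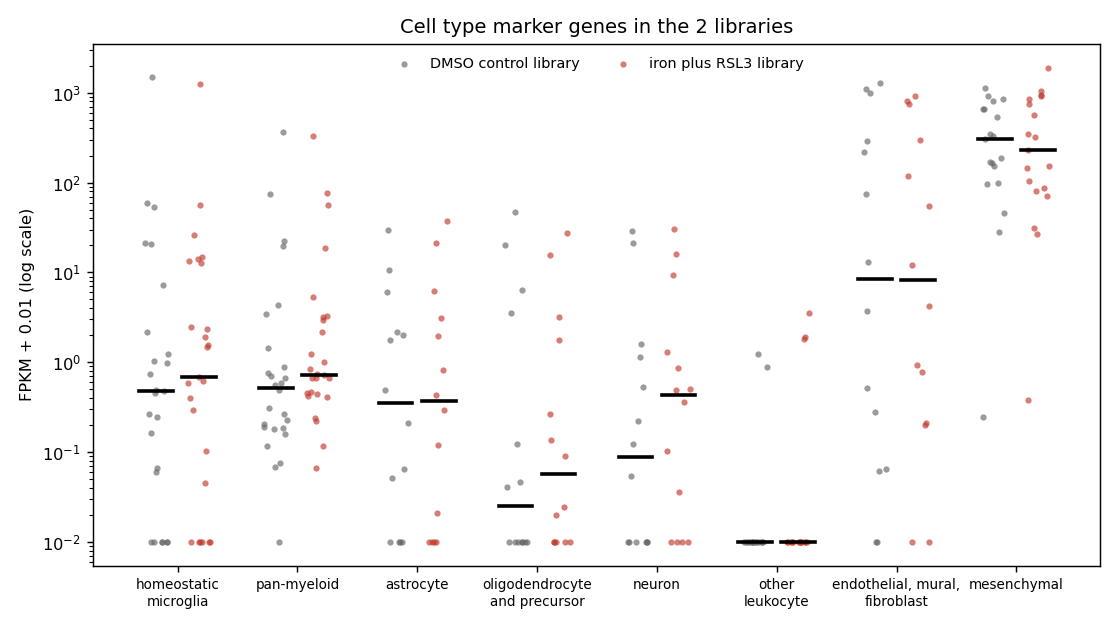
FPKM + 0.01 (y axis, log scale) of the members of 8 marker lists (x axis) in the DMSO control library (grey) and the iron plus RSL3 library (red). Points are genes and black bars are list medians; pan-myeloid genes have medians of 0.51 and 0.72 FPKM, and mesenchymal genes 304 and 231.3 FPKM.

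Of 12 measured homeostatic genes, 1 was higher and 1, Tmem119, was lower (59.1 and 26.1 FPKM, under 2-fold after centring). The median of 0.20 lay at the 99.7th percentile, and it turned to -0.26, at the 51.5th, among members at 5 FPKM or more. Of 23 disease-associated microglia genes, 3 were higher, including the lysosomal glycoprotein gene Cd68 (3.36 and 10.4 FPKM) and Ccl6 (3.04 and 8.24 FPKM), with a median of 0.19 at the 95.01st percentile. With random lists also matched on transcript length this became the 99.3rd percentile, and the lists of phagocytosis and alternative activation genes likewise came to lie above the central 95%, at the 98.1st and 97.9th. Of 15 phagocytosis and complement receptor genes, 1, Cd68, was higher, with a median of 0.11 at the 96.3rd percentile that became -0.049 with equal totals. Of 26 lysosome and autophagy genes, 3 were higher, led by Sqstm1, the autophagy receptor gene (239.9 and 1950.1 FPKM), and Ctss (4.63 and 16.2 FPKM), with a median of 0.23 at the 98.9th percentile. Of 15 MHC and antigen presentation genes, 1, H2-Ab1, was higher (0.25 and 1.97 FPKM), with a median of 0.05 at the 88.7th percentile that became -0.11 with equal totals. Of 7 alternative activation markers, 1, Socs3, a suppressor of cytokine signalling, was higher (3.16 and 23.0 FPKM), with a median of 0.16 at the 96.9th percentile. Beside these lists too, 3 of the 11 measured pan-myeloid genes were at least 2-fold higher in the treated library.

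Markers of astrocytes, oligodendrocyte lineage cells, neurons and other leukocytes were mostly low. Of 14 endothelial, mural and fibroblast markers, 7 reached 10 FPKM and 5 reached 100 FPKM in both libraries. Measured markers other than Nefm and Cd79a stayed within 2-fold. Astrocyte markers had 6 of 14 measured and none past 2-fold, with a median of 0.19 at the 98.3rd percentile, or the 97.4th among random lists also matched on transcript length. The highest were Gja1 (30.01 and 37.2 FPKM) and Sox9 (10.8 and 21.1 FPKM, past 2-fold after centring). Of the oligodendrocyte lineage markers 4 were measured, too few for a percentile, with Pdgfra at 47.4 and 27.4 FPKM and Cspg4 at 19.98 and 15.6 FPKM. Of 5 measured neuron markers, Nefm, a neurofilament gene, was higher (0.04 and 9.43 FPKM), and the median was -0.18, at the 78.2nd percentile. Of 8 measured endothelial, mural and fibroblast markers none passed 2-fold, with a median of -0.33 at the 3.18th percentile that became -0.41 at the 0.56th at 5 FPKM or more. Of 3 measured markers of other leukocytes, Cd79a, listed at 0 in the control, was at 3.502 FPKM in the treated library.

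Lipid genes split in direction. Of 25 cholesterol synthesis and LDL uptake genes, 2 were at least 2-fold higher and 2 lower. Insig1, a brake on sterol synthesis, was at 51.8 and 299.2 FPKM and Pmvk at 15.5 and 39.9 FPKM. Dhcr7 (20.1 and 7.90 FPKM) and Mvk (36.4 and 17.1 FPKM) were lower, Mvk under 2-fold after centring. The median of 0.05, at the 97.7th percentile, became -0.10 with equal totals, and among genes at 5 FPKM or more it lay at the 97.2nd. Of 19 fatty acid and lipid droplet genes, 2 were higher, the lipid droplet gene Hilpda (12.3 and 79.3 FPKM) and the triglyceride synthesis gene Dgat2 (2.495 and 11.9 FPKM), with a median of -0.24 at the 68.6th percentile. Of 9 cholesterol efflux genes, 1, Mylip, was higher (6.61 and 14.8 FPKM), though under 2-fold with equal totals, and the median was -0.22 at the 74.6th percentile. Of 21 growth factor and matrix protease genes, 6 were higher and 1 lower. Vegfa, the angiogenic growth factor gene, was at 25.9 and 228.9 FPKM, and the matrix glycoprotein gene Thbs1 at 1615 and 797.7 FPKM, under 2-fold after centring. The median of that list was 0.17, at the 98.2nd percentile, or the 96.1st at 5 FPKM or more.

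Of 15 common reference genes, 2 were at least 2-fold higher, 1 was lower and 12 lay between, with a median of 0.00 at the 53.99th percentile that became -0.15 with equal totals. Actb, the cytoplasmic actin gene, was at 1162 FPKM in the control and 299.8 FPKM in the treated library, 3.87 times lower. Gapdh was at 16.1 and 73.2 FPKM, and it has many processed pseudogenes that can share its reads, so its level is uncertain. Eef1a1 (3695 and 5068 FPKM) and B2m (2826 and 4018 FPKM) were among the most abundant transcripts and stayed within 2-fold.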

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

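The 2-fold counts were 500 higher and 1384 lower. With a pseudocount of 0.1 FPKM 2379 genes were lower, with 5 FPKM 301 were higher and 209 lower, centred on the median ratio 765 were lower, and at 4-fold 165 were higher and 26 lower. Higher genes made up 26.5% of those past 2-fold, 59.0% with the pseudocount of 5 FPKM, 46.5% after centring and 86.4% at 4-fold. A larger pseudocount shrinks the log2 changes of weakly expressed genes by construction. Among genes with an annotated length, 323 were 2-fold lower in the 20% with the lowest mean FPKM and 63 in the highest 20%. Genes 2-fold higher numbered 76 and 162 there. Leaving out genes under 5 FPKM gave 28.9% higher, which cannot decide the matter because a pseudocount of 5 FPKM also shrinks genes above that filter. The cause of the change in share was not tested further. Centring moved the median of all measured genes from -0.38 to -0.19. Pearson's r of 0.92 became 0.97 without a filter, 0.89 at 5 FPKM or more and 0.90 with the pseudocount of 0.1 FPKM. Spearman's rho of 0.92 became 0.95 without a filter and 0.87 at 5 FPKM or more. The lists with a median above the central 95% of random lists numbered 17, and 12 to 20 under the alternatives, including 20 with random lists matched on length in 5 bins and on expression in 10 in place of 20 bins, so that 2 choices differ, an alternative chosen after seeing the data. Below it lay 1 list, and 2 at 5 FPKM or more. Among lists outside the central 95%, medians that turned sign were those of inflammatory genes (-0.024 at 5 FPKM or more, -0.048 with equal totals), homeostatic microglia (-0.26 at 5 FPKM or more) and cholesterol synthesis (-0.10 with equal totals, -0.028 without the mitochondrial and 20 top genes); apart from the dropped members the cause was not tested. At 5 FPKM or more, the medians of inflammatory genes, homeostatic microglia, chemokines, cholesterol synthesis and growth factors came to lie within the central 95% and that of endothelial, mural and fibroblast markers below it, and some lists, astrocyte markers among them, had too few members left for a value. Glutathione and thioredoxin enzymes came to lie above it under several alternatives, and alternative activation markers without the mitochondrial and top genes. Of the 105 named genes, none past 2-fold changed sign under the alternatives run for them, 8 fell short of 2-fold and 3 passed it after centring, 2 fell short with equal totals, and 1 passed with a pseudocount of 0.1 FPKM. Depth limits genes near 1 FPKM. No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out.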

Other observations

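The tests in this part were set out before the values that decide them were seen, but each pattern had been noticed in these data first. Targets of YAP and SRF, transcriptional regulators that respond to mechanical tension, had a median log2 change of -0.70 over 23 genes, of which 10 were at least 2-fold lower and 13 lay between. Besides Ctgf and Actb, the matricellular gene Cyr61 was at 384 FPKM in the control and 114.3 FPKM in the treated library, the Hippo kinase gene Lats2 at 46.0 and 17.1 FPKM, and Vcl, which encodes the focal adhesion protein vinculin, at 134.4 and 56.0 FPKM. Leaving out the 6 members whose values had prompted the list, 15 of 17 genes had a log2 change below 0, 5 were at least 2-fold lower and none was 2-fold higher. Their median of -0.65 lay below all 10000 matched random lists, whose central 95% ran from -0.27 to 0.30. Markers of endothelial, mural and fibroblast cells had a median of -0.33 at the 3.18th percentile, and mesenchymal genes a median of -0.02 at the 15.3rd. A lower activity of these regulators at the listed genes, as in cells that round up or detach, is a hypothesis. With 1 library per condition it cannot be tested further, and a change in the mix of cells stays open. SRF also drives immediate early genes such as Fos (3.02 and 77.2 FPKM), which is not on this list. Of 22 immediate early genes, 18 were at least 2-fold higher, with a median of 2.79. The fall therefore did not extend to Fos. The immediate early list was not made as a list of SRF targets, so SRF targets outside the YAP and SRF list were not tested as a group.

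The marker profile is the result to look at first, since the libraries are labelled primary microglia. Pan-myeloid genes such as Ptprc, Spi1, Fcer1g and Lyz2 had a median of 0.51 FPKM in the control and 0.72 FPKM in the treated library, and mesenchymal genes medians of 304 and 231.3 FPKM. A candidate explanation is that few cells in either culture were myeloid, and the values meet what it predicted, a pan-myeloid median under 5 FPKM beside a mesenchymal median over 50 FPKM, although macrophages also express some of the latter genes, such as Vim and Lgals1. Microglia that had lost homeostatic markers in culture but kept the genes of all myeloid cells were predicted to have a pan-myeloid median over 20 FPKM, and the tables argue against this as the main content of the libraries. Of the 4 pan-myeloid genes at 10 FPKM or more in both libraries, Cyba (75.2 and 76.8 FPKM) and Arhgdib (363.8 and 331.2 FPKM) are also expressed outside myeloid cells, while Lyz2 (19.9 and 56.3 FPKM) and Mpeg1 (22.4 and 18.9 FPKM) are largely myeloid, so some myeloid cells may be present, and a mislabelled pair of libraries stays open.

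Several myeloid transcripts were higher in the treated library: C1qa 3.88 times, Fcer1g 3.93 times, Spi1 3.69 times, Trem2 3.24 times and Lyz2 2.82 times, chosen after their values had been seen. On the scale used elsewhere, the 11 measured pan-myeloid genes had a median log2 change of 0.50, at the 99.92nd percentile of matched random lists. Over the 19 pan-myeloid genes at 0.5 FPKM or more, 68.4% had a log2 change above 0. The median log2 change of these 19, with a pseudocount of 0.1 FPKM, was 0.93, at the 99.99th percentile. The scale of the deposited values is argued against as the whole cause, since the median of these 19 genes was 1.10 after centring and 0.80 with equal totals. Either scaling shifts all genes by a similar small amount, so this outcome followed from the size of the median and is no separate test. A larger share of surviving myeloid cells had been predicted to raise at least 80% of these genes, and a share under 60% would have spoken against it, so the observed value leaves it open. Induction of these genes within the cells is untested.

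Most genes were lower in the treated library, with a median log2 change of -0.38. Setting equal totals alone moved it to -0.51, and leaving out the mitochondrial and 20 most abundant genes as well gave -0.45. The 20 most abundant genes held 10.1% of the control and 14.7% of the treated total, so leaving them out could move the median only a little. These shares argue against these few genes as the whole cause, and the recalculation adds no separate test. Transcript length is argued against, since the median was -0.30 in the 20% of genes with the shortest transcripts and -0.44 in the 20% with the longest. GC content is argued against as well, since the medians of the 20% of genes with the lowest and the highest content were -0.37 and -0.34. The shift was weakest among abundant genes, at -0.09 in the 20% with the highest mean FPKM and -0.49 in the 20% with the lowest, and a broad gain of many abundant transcripts, or a loss of RNA from the others, stays open without an external standard.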
